A study of Mus musculus with 8 samples.

How the data were processed

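RNA from mouse lumbar dorsal root ganglia was sequenced in 8 libraries, each from ganglia L3 to L5 of 3 pooled mice, per the labels' protocols: the injured and the uninjured side at days 1, 3 and 7 after ligation of the left L4 spinal nerve, and the left and right side of a pool labelled no injury. The deposited table holds whole-number read counts per gene for 53801 Ensembl genes and all 8 of its columns were used. Per the submitters' processing notes, which name tools without their role, cutadapt 1.16, STAR 2.5.4a, featureCounts 1.6.3 and DESeq2 were used with the build GRCm38. The strand setting, the handling of reads that fit several genes and the annotation release are not given in the sources used here, so reads of overlapping, antisense or near-identical genes cannot be told apart. Counts were used as deposited. Gene names, biotypes and positions came from GENCODE release M21 (GRCm38), which matched 53706 of the gene IDs.

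Total counts ran from 20488115 to 21652688 per library, close enough that depth differs little between groups; 3 reads, the limit that a count of 0 allows, equal about 0.14 CPM. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. No library pair agreed within sampling noise: the lowest chi-square per gene was 6.43, between the left and right libraries labelled no injury.

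The main test was edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test with robust shrinkage, TMM factors, filterByExpr with a minimum count of 10, Benjamini-Hochberg adjustment at 0.05). The injury effect was fitted over all 8 libraries with the pool of mice as a block and injured state as the term of interest (3 residual degrees of freedom), so its error is the spread of the side difference between pools, differences in time included, and the p-values measure the spread between these pools. The time trend added injured state by centred log2 of the day (2 residual degrees of freedom). The contralateral libraries were compared with the libraries labelled no injury, summed to 1 sample that is assumed to vary like the others (2 residual degrees of freedom). Ratios of sides within a pool used TMM-normalised log2 CPM with a prior count of 2, genes with at least 50 reads in the higher library and a 2-fold limit, and have no test. The pool block follows from the design text, which makes each mouse its own control; deviations of the sides from their state means correlated by 0.249, -0.0618 and 0.356 within the pools of days 1, 3 and 7.

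Before the data were examined, 30 gene lists were fixed. The cell type lists are nociceptors, large-fibre neurons, macrophages, neutrophils, lymphocytes, satellite glia, myelinating and repair Schwann cells, extracellular matrix and fibroblasts, endothelial and mural cells, skeletal muscle, erythroid cells, adipocytes, central nervous system glia and pan-neuronal genes. The others are injury and regeneration genes, injury neuropeptides, potassium channels, sodium, calcium and HCN channels, opioid, GABA and inhibitory receptors, nicotinic receptors, cell cycle, chemokines and cytokines, complement, interferon-induced genes, antigen presentation, sterol synthesis, the unfolded protein response, immediate early genes and mitochondrially encoded genes. Of their 633 genes 631 were in the table. Lists were tested with camera (limma 3.58.1, two-sided, preset correlation 0.01), and per time point each list's median log2 ratio was ranked among 10000 random lists matched on mean expression in 20 bins.

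Most of the named genes followed a rule fixed beforehand: for the injury effect the 12 largest rises and 12 largest falls among genes with adjusted p under 0.05 and the same sign in 3 pools; for the trend and the contralateral comparison the 4 largest each way among genes past that threshold, or else the 3 lowest p each way as values only; for each pool the 4 highest and 4 lowest side ratios; for each list up to 4 genes with the lowest p; and Atf3, Sprr1a, Gal, Npy and Csf1. Gabra2, members named as exceptions within a list and the genes of the closing section were chosen after their values were seen. Predicted genes and pseudogenes were counted and not named.

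The scripts were tested on simulated counts drawn from the real means and library sizes with changed genes planted. For the injury effect, run on 15980 genes, 60% of genes changed 1.5-fold, 84% changed 2-fold, 100% changed 4-fold and 98% changed 8-fold were recovered. For the trend, on 15984 genes, the shares were 60%, 92%, 98% and 98% for such changes per doubling of days, and for the contralateral comparison, on 16096 genes, 34%, 76%, 98% and 100%. In these runs 15 of 186, 24 of 198 and 12 of 166 calls were of genes without a planted change. With no change planted the 3 tests called 1, 9 and 0 genes. All libraries were drawn from 1 mean per gene, with no difference between pools. The contralateral test compares pools, so its recovery holds only for pools that do not differ otherwise. Across the genes tested, the log2 fold change of the injury effect had a Spearman correlation of 0.0814 with GC content and -0.00411 with exon length.

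Alternatives covered other scalings (RLE, upper quartile, total counts), DESeq2 1.42.0, limma-voom, other filters, pools or libraries left out, the fit with no block, side as a covariate, other thresholds and controls, prior counts, read minimums and list tests. Scaling moved the median log2 fold change of all genes from 0.016 with TMM to 0.011 with RLE and -0.005 with upper-quartile factors. A few genes among the largest differences and list members are not reported here.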

Results

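Gene expression was measured by RNA sequencing in lumbar dorsal root ganglia of the mouse after spinal nerve ligation. The dorsal root ganglia hold the cell bodies of the sensory neurons together with satellite glia, Schwann cells, resident macrophages and vessels, and tight ligation of a spinal nerve cuts off their peripheral axons. Per the labels the left L4 nerve of male C57BL/6J mice was ligated and ganglia L3 to L5 were collected from both sides, so each injured-side library also holds 2 neighbouring ganglia whose nerve was not tied. Each library pooled 3 mice. At days 1, 3 and 7 there was 1 library of the injured side and 1 of the uninjured (contralateral) side of the same mice, and a further pool labelled no injury gave 1 left and 1 right library, 8 libraries in all. Total counts lay between 20488115 and 21652688 reads per library. No time point has a second library of a side, so the 3 injured pools served as replicates of the injured state and a difference at a single day has no replicate check.

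The labels were checked first with 5 genes known to rise after nerve injury, taken in every library. Atf3, a stress-induced transcription factor of axotomised neurons (chromosome 1), reached 464, 629 and 618 CPM on the injured side at days 1, 3 and 7, against 126, 167 and 110 CPM on the contralateral side and a mean of 10.9 CPM in the libraries labelled no injury. Sprr1a, a growth-associated protein, went from 9.13 CPM at day 1 to 466 at day 3 and 915 at day 7 on the injured side and from 3.52 to 126 and 130 CPM on the contralateral side, with a mean of 0.234 CPM without injury. The neuropeptides galanin (Gal) and neuropeptide Y (Npy) reached 536 and 127 CPM at day 7 on the injured side and 83.5 and 18.4 CPM on the contralateral side. Csf1, the macrophage growth factor, stood at 205 CPM against 45.8 CPM at day 7. In all 3 operated pools each of the 5 genes was higher on the injured side, as the labels say. The contralateral level was above the mean of the libraries labelled no injury for each gene at each day. The sex given by the labels did not hold for the libraries labelled no injury: Xist, transcribed from the inactive X of females, had 4931 and 4129 reads there and at most 3 reads in each operated library, and Y-linked Kdm5d had 0 reads there and 13.1 to 16.7 CPM elsewhere.

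**Figure D1:**
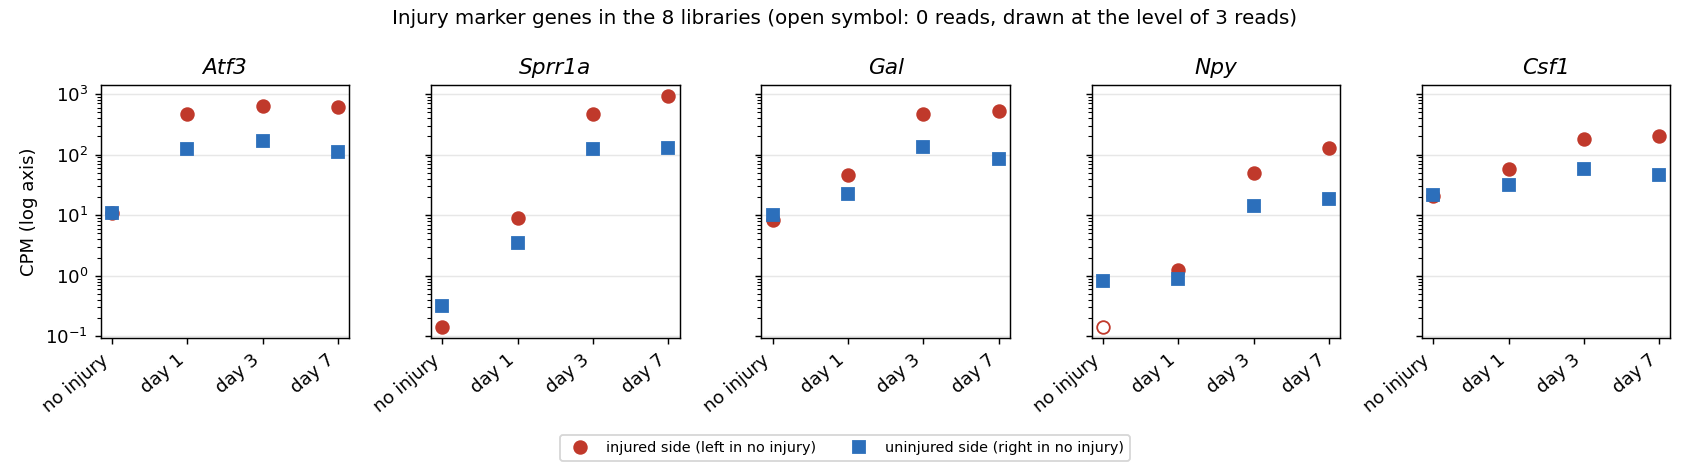
CPM of Atf3, Sprr1a, Gal, Npy and Csf1 (log axis) in the 8 libraries, 1 point per library with no error bar since each is a single library: red circles for the injured side (left side in the pool labelled no injury), blue squares for the uninjured side (right side there). Sprr1a on the contralateral side went from 3.52 CPM at day 1 to 130 CPM at day 7, below the injured side at each day.

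The main question was which genes differ between the injured and the uninjured ganglia of the same mice. Against the uninjured side, the largest fitted rises were in genes that were scarce without injury. This ranking understates the rise over the libraries labelled no injury for genes also raised on the contralateral side. At day 7 Atf3 was 5.61-fold over the contralateral side and 56.45-fold over the mean of the libraries labelled no injury. For Sprr1a these values were 7.05-fold and 3911-fold. Ucn2, a peptide of the corticotropin-releasing family (chromosome 9, 108986010 to 108987164, GRCm38), was 8.22-fold higher on the injured side (log2 fold change 3.04 ± 0.47, SE, 3 injured pools; edgeR quasi-likelihood adjusted p = 0.00722). Lipn, a lipase gene (chromosome 19), rose 5.54-fold to a mean of 13.2 CPM over the injured pools. It was at 0.250 CPM on the injured side at day 1, 17.8 at day 3 and 21.5 at day 7. The transcription factor gene Phox2a rose 6.32-fold, the acute-phase gene Saa2 5.64-fold, the keratin Krt16 5.33-fold, and Tmprss11f, Bpifc, Crocc2, Sh2d1b2 and Ankrd1 between 5.38-fold and 7.37-fold. With side as a further term Tmprss11f had a log2 value of -0.30. The pool labelled no injury alone sets that term, and the gene was near absent there, at 0.0479 CPM left and 0 right. Saa2 has a near-identical neighbour, so its reads could be split between copies. Apart from Lipn these genes stayed at a mean of 3.99 CPM or less on the injured side.

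The falls were smaller and also led by scarce genes. Wfdc5 fell to 0.205 of the uninjured level (log2 fold change -2.29 ± 0.44, SE; adjusted p = 0.0149), Atp1a4, an ion pump subunit, to 0.321 and Mmrn1 to 0.323. The serotonin receptor gene Htr2c fell to 0.408, the BMP antagonist Grem1 to 0.375, Angpt4 to 0.403, Klk5 to 0.409, Zfp750 to 0.356 and the bile acid transporter gene Slc10a2 to 0.42, although Slc10a2 stood 0.66 (log2) higher when set against the libraries labelled no injury alone. Iglc2, an immunoglobulin light chain gene that shares sequence with its neighbours, fell to 0.187. Uckl1os and Kcnd3os are antisense to other genes, and because the strand setting of the counting is not given in the sources used here their reads could come from the partner gene. None of these 12 genes had a mean above 0.751 CPM on the injured side.

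Of 16244 genes tested, 1644 were higher and 1302 lower on the injured side at an adjusted p under 0.05 (edgeR), 298 and 47 of them by 2-fold or more, and the median fold was 1.40 for the higher and 0.747 for the lower genes. The side ratio had the same sign in all 3 pools for 1641 of the higher and 1302 of the lower genes. Predicted genes and pseudogenes made up 62 and 91. Without the day 7 pool the calls were 475 higher and 156 lower, without day 3 they were 651 and 334, without the pool labelled no injury 763 and 449, and without day 1 they were 2382 and 2287. With side as a further term, which sets the injured pools against the left-right difference of the single pool labelled no injury, 6 genes were higher and 0 lower by edgeR, against 879 and 641 at an unadjusted p under 0.05, with 62 and 7 called by DESeq2 and 10 and 0 by limma-voom, and when the test asked for more than a 1.5-fold change 54 were higher and 4 lower.

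**Figure D2:**
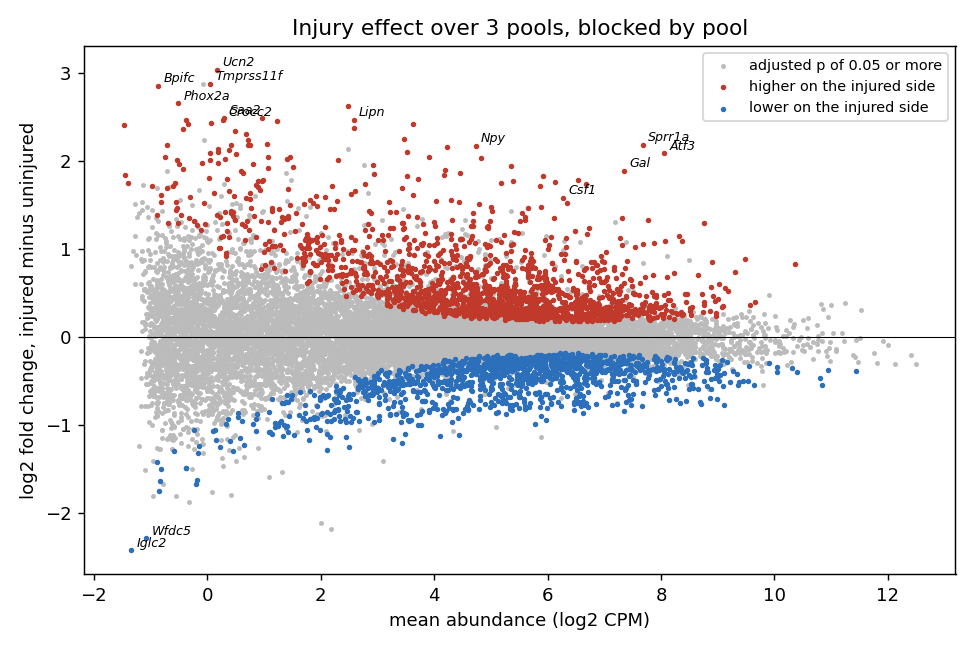
Fitted log2 fold change (injured minus uninjured side) of the 16244 genes tested against mean abundance in log2 CPM, 1 point per gene, without error bars. Red points are the genes higher and blue points those lower at an adjusted p under 0.05; the abundant injury markers Atf3, Sprr1a and Gal lie at log2 fold changes of 2.09, 2.19 and 1.89.

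**Figure D3:**
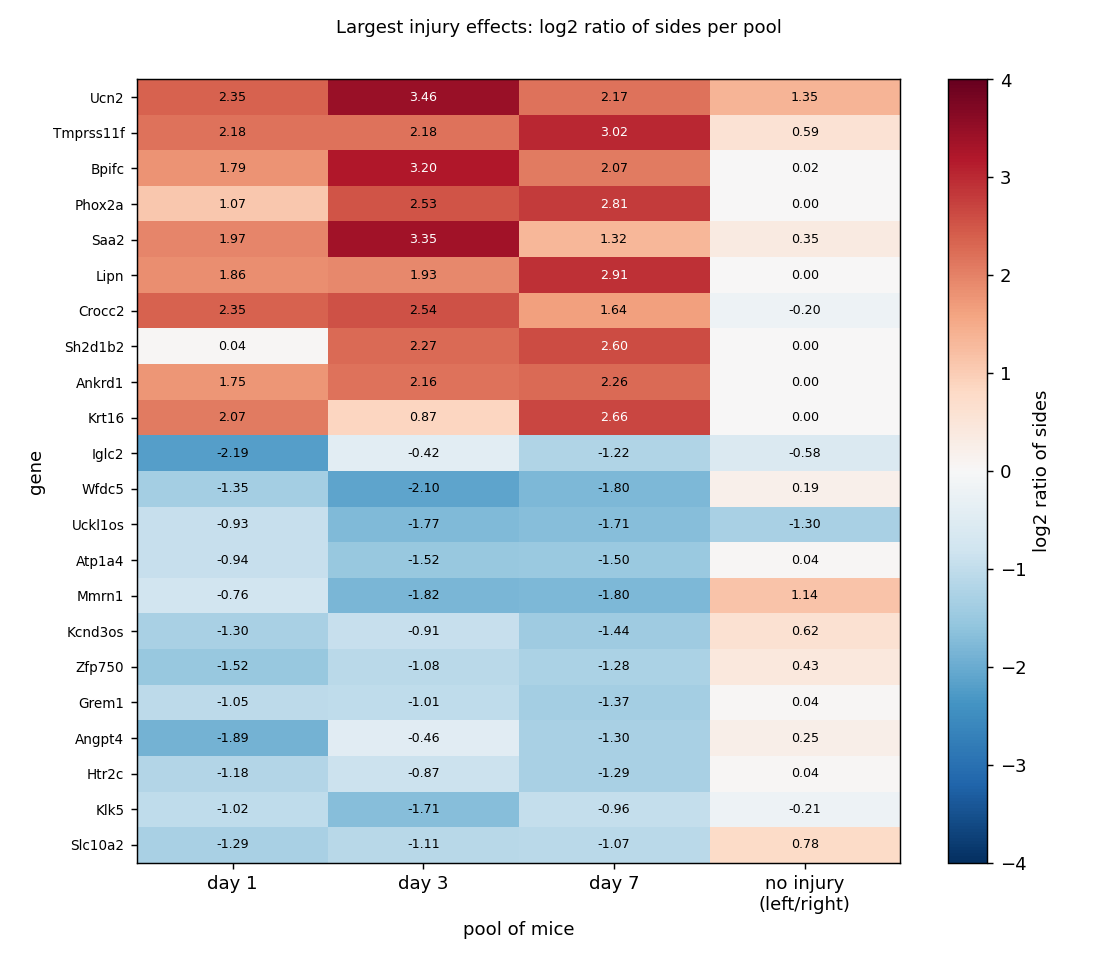
Log2 ratio of the injured over the uninjured side at days 1, 3 and 7, and of left over right in the pool labelled no injury, for 10 of the 12 genes with the largest rise and the 12 with the largest fall; each cell is 1 pair of libraries. Ucn2 had ratios of 2.35, 3.46 and 2.17 after injury and 1.35 without, and Sh2d1b2 stood at 0.04 at day 1 and 2.60 at day 7.

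Genes known to respond to axon injury rose as a group. Of the 30 injury and regeneration genes tested, 27 rose, 0 fell and 3 were not called (29 higher and 1 lower when adjusted over the list alone), with a median log2 fold change of 1.20. The growth-arrest gene Gadd45a rose by 1.74 ± 0.09 (log2, SE; adjusted p = 4e-04), the adhesion gene Flrt3 by 1.78 ± 0.10, the cytokine signalling inhibitor Socs3 by 1.26 ± 0.08 and the transcription factor Jun by 1.03 ± 0.06, each in 3 of 3 pools. Gap43, Klf7 and Lifr had log2 values of 0.88, 0.23 and -0.17 with adjusted p of 0.0553, 0.0646 and 0.111. Of the 8 injury neuropeptides tested, 6 rose and 1, Nmb, fell (6 and 1 adjusted over the list alone). Adcyap1, which encodes PACAP, rose by 1.33 ± 0.06, Crh by 2.05 ± 0.27, Nts by 1.41 ± 0.21 and Penk by 0.46 ± 0.10. Both lists passed camera, a test of a list against the other genes, with a preset correlation (adjusted p = 6.38e-58 and 5.19e-07); adjusted p = 0.177 for each with an estimated correlation.

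Of 15 immediate early genes 10 rose (13 adjusted over the list alone), among them Dusp1 (log2 0.89 ± 0.11, SE) and Junb (0.53 ± 0.07), and adjusted p = 0.486 with an estimated correlation. Of 22 unfolded protein response genes 11 rose (15 adjusted over the list alone), including Atf4 by 0.40 ± 0.05, Xbp1 by 0.41 ± 0.06 and Chac1 by 1.07 ± 0.17; adjusted p = 0.378 with an estimated correlation. Of 30 interferon-induced genes 16 rose (19 adjusted over the list alone), including Irf7 (0.86 ± 0.11), Oasl2 (0.62 ± 0.08) and Ifi44 (0.99 ± 0.16), with adjusted p = 0.486 with an estimated correlation. In the antigen presentation list 3 of 17 rose (4 adjusted over the list alone), H2-D1, Psmb8 and B2m; adjusted p = 0.679 with an estimated correlation. In the sterol synthesis list 5 of 24 rose (7 adjusted over the list alone), among them Mvd by 0.38 ± 0.07; adjusted p = 0.698 with an estimated correlation.

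Of 25 extracellular matrix and fibroblast genes 11 rose (19 adjusted over the list alone), led by Timp1, an inhibitor of matrix proteases (log2 2.16 ± 0.21, SE), Postn (1.06 ± 0.17) and Mmp2 (1.15 ± 0.19); adjusted p = 0.486 with an estimated correlation. Against the libraries labelled no injury alone Timp1 stood at 4.74, and Postn at 0.35 and Mmp2 at 0.44 were not called. That comparison has no pool block and enters the left and right library of a single pool as separate controls. Its calls therefore rest on another error than those of the main test. Of 144 named genes 49 moved by more than 1.5 times in that comparison and 67 lost their call, among them Ccl7 with a smaller value (1.48 there) and Ccl8 and Ccl2 with larger ones (2.66 and 2.17). Of 25 macrophage genes 5 rose (6 adjusted over the list alone), among them Cd163 (0.98 ± 0.13), Cd14 (1.13 ± 0.22), Ms4a7 (1.36 ± 0.27) and Gpnmb (0.87 ± 0.18), and adjusted p = 0.58 with an estimated correlation. The chemokines Ccl7 (2.20 ± 0.30), Ccl8 (1.71 ± 0.28) and Ccl2 (1.61 ± 0.28) were among 6 of 21 chemokine and cytokine genes that rose (7 adjusted over the list alone); adjusted p = 0.58 with an estimated correlation. In the complement list 4 of 14 rose, including C4b (0.66 ± 0.10) and C3ar1 (1.46 ± 0.34), while Cd55, which restrains complement on the cell surface, fell by 0.76 on the log2 scale (8 higher and 1 lower adjusted over the list alone); adjusted p = 0.528 with an estimated correlation.

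Of 16 satellite glia genes 6 rose (6 adjusted over the list alone), with Gfap, an intermediate filament of reactive glia, at 1.41 ± 0.15 and Lgi4 at 0.58 ± 0.08; adjusted p = 0.486 with an estimated correlation. Of 13 repair Schwann cell genes 5 rose (9 adjusted over the list alone), including the GDNF receptor gene Gfra1 (1.10 ± 0.14), Lif (1.64 ± 0.37) and Gdnf (2.10 ± 0.49); adjusted p = 0.486 with an estimated correlation. Gdnf had a side ratio of only 0.17 at day 7. In the myelinating Schwann cell list 1 of 19 rose (0 adjusted over the list alone; adjusted p = 0.714 with an estimated correlation), and in the endothelial and mural list Cspg4 and Kdr of 20 (1 adjusted over the list alone; adjusted p = 0.698 with an estimated correlation). Against the libraries labelled no injury alone Kdr had a log2 value of -0.20.

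Of 30 nociceptor genes 10 fell and 1 rose (16 and 3 adjusted over the list alone). The itch receptor gene Mrgpra3 fell by 0.81 on the log2 scale (SE 0.12), Mrgprx1 by 0.52 and Lpar3 by 0.80, while Gfra3, the artemin receptor gene, rose by 0.68. The Mrgpr genes form a large family whose members can share reads. Of 20 large-fibre neuron genes 14 fell and 1, Spp1, rose (16 and 1 adjusted over the list alone). Etv1 fell by 0.79 (SE 0.09), the sodium channel genes Scn1a and Scn8a by 0.74 and 0.53, and Runx3 by 0.60. Of 22 pan-neuronal genes 7 fell and 1, Elavl3, rose (10 and 3 adjusted over the list alone), with a median of -0.19; Pou4f3, Pou4f2 and Isl1, transcription factors of sensory neurons, fell by 0.75, 0.94 and 0.40. These 3 lists had adjusted p of 0.58, 0.486 and 0.58 with an estimated correlation.

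The widest fall among the channel lists was that of potassium channels, where 21 of 37 genes fell and 1, Kcnmb4, rose (25 and 1 adjusted over the list alone). Kcns1 fell by 0.80 on the log2 scale, Kcna2 by 0.77, Kcnip1 by 0.68 and Kcnk18 by 0.62, each in 3 of 3 pools; adjusted p = 0.499 with an estimated correlation. Of 26 opioid, GABA and inhibitory receptor genes 12 fell and 2, Gabra5 and Adra2a, rose (14 and 2 adjusted over the list alone). Gabrb2 fell by 0.99, the nociceptin receptor gene Oprl1 by 0.82, the muscarinic receptor gene Chrm2 by 0.82 and Adra2c by 0.81; adjusted p = 0.486 with an estimated correlation. Of 24 sodium, calcium and HCN channel genes 5 fell (5 adjusted over the list alone), Cacna1i by 0.86 and Scn4b by 0.56 among them, with adjusted p = 0.58 with an estimated correlation.

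With camera's preset correlation 15 of the 30 lists were higher and 6 lower, the lists described so far; other splits of the same libraries gave up to 24 called lists. The other 9 did not pass. In the nicotinic receptor list (camera adjusted p = 0.084) Chrna6 fell by 0.99 and Chrna5 rose by 1.57 (2 and 2 adjusted over the list alone). In the central nervous system glia list Aldh1l1, Tmem119 and P2ry12 rose, 3 of 8 (4 adjusted over the list alone; camera adjusted p = 0.169), and Tmem119 stood at -0.04 with side as a further term. In the lymphocyte list Cd79a, a B cell gene, fell by 1.24 (1 of 8, and 1 adjusted over the list alone; adjusted p = 0.296), and in the adipocyte list Lipe rose (1 of 12, and 1 adjusted over the list alone; adjusted p = 0.985). No member was called, nor adjusted over the list alone, among 14 neutrophil, 19 skeletal muscle, 9 erythroid, 30 cell cycle and 7 mitochondrially encoded genes (camera adjusted p = 0.295, 0.895, 0.494, 0.578 and 0.521). The skeletal muscle list had a median of 0.14 and a mean of 0.09 although camera gave it a downward direction. None of the 30 lists passed with an estimated correlation, and by fry, which asks whether a list's genes move on balance 1 way, 3 passed: injury and regeneration genes, injury neuropeptides (adjusted p = 0.0193 each) and unfolded protein response genes (0.0201).

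**Figure D4:**
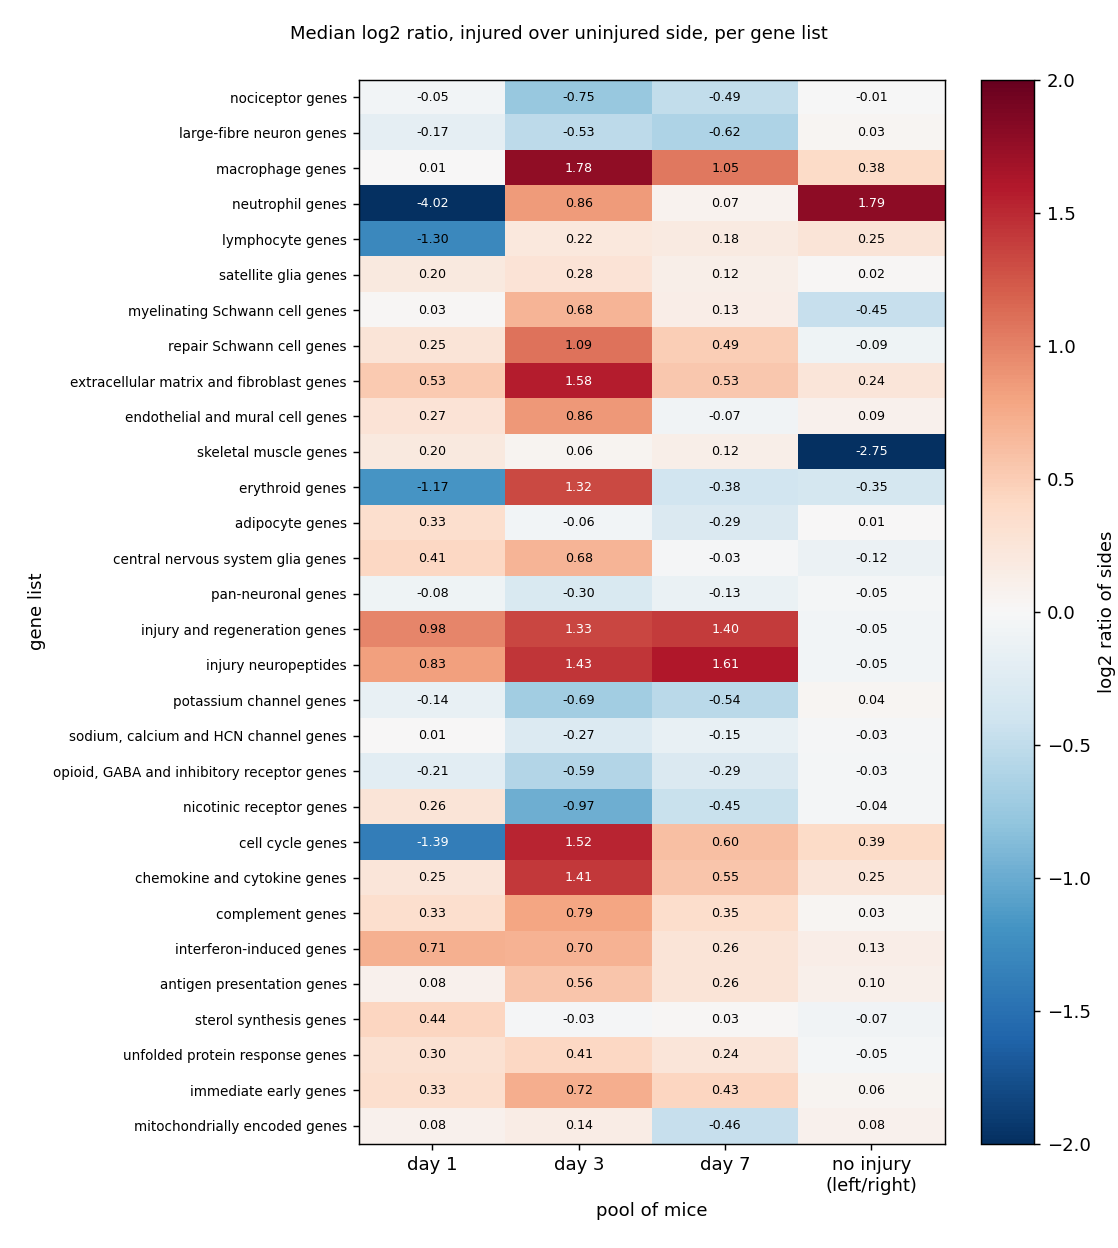
Median log2 ratio of the injured over the uninjured side for each of the 30 gene lists at days 1, 3 and 7, and of left over right in the pool labelled no injury; each cell is the median over a list's genes in 1 pair of libraries, without error, and colours saturate at 2 either way. Injury and regeneration genes had medians of 0.98, 1.33 and 1.40, macrophage genes 0.01, 1.78 and 1.05, and neutrophil genes -4.02 at day 1.

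The time points were next described singly, by the ratio of the 2 sides, with no test. At day 1, 122 genes were at least 2-fold higher and 192 at least 2-fold lower on the injured side, of 13267 genes with 50 reads or more in either library. Among the highest log2 ratios were those of Crocc2 (2.35), Ucn2 (2.35) and the growth factor Areg (2.19). The lowest were Elane (-5.74) and Mpo (-5.61), which encode granule enzymes of neutrophil precursors, Ctse (-5.21) and the red cell anion exchanger gene Slc4a1 (-5.13). The uninjured library stood apart there for Mpo, at 24.1 CPM in it and at most 1.83 CPM in the 7 others. Of 14 neutrophil genes 12 had their highest level of all libraries in it. The left library labelled no injury lay closer to it for some of them. Ltf was at 33.1 CPM there against 35.7, S100a9 at 112 against 211 and Csf3r at 4.53 against 4.37, but Elane at 0.482 against 7.61. At day 1 the neutrophil list had a median of -4.02, the cell cycle list -1.39, the lymphocyte list -1.30 and the erythroid list -1.17. Injury and regeneration genes were at 0.98, interferon-induced genes at 0.71 and sterol synthesis genes at 0.44. Each of the last 3 was at the 100th percentile of 10000 random lists matched on expression. Left over right without injury, interferon-induced genes were at percentile 99.69 with a median of 0.13. Injury and regeneration genes were at 1.75 there and sterol synthesis genes at 0.47.

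At day 3, 855 genes were at least 2-fold higher and 145 at least 2-fold lower, of 13448. Cxcl14 had the highest log2 ratio (4.13), followed by Clca3a2 (3.84), the stem cell receptor gene Lgr6 (3.70) and Il17b (3.65), and the lowest were the nicotinic subunit gene Chrnb4 (-2.16), Slc51a (-2.02), Nell1 (-1.67) and Bnc1 (-1.66). Macrophage genes had a median of 1.78, extracellular matrix genes 1.58, cell cycle genes 1.52 and chemokines 1.41. Erythroid genes were at 1.32 and repair Schwann cell genes at 1.09, and all these lists were at the 100th percentile. Nociceptor genes were at -0.75, potassium channel genes at -0.69 and nicotinic receptor genes at -0.97. Left over right without injury, macrophage, extracellular matrix and cell cycle genes were also at the 100th percentile and chemokines at 99.81. Their medians there were smaller, at 0.38, 0.24, 0.39 and 0.25. Erythroid and repair Schwann cell genes were at percentiles 0 and 2.585 there. So high a percentile is thus reached without injury and is no sign of injury by itself.

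At day 7, 411 genes were at least 2-fold higher and 97 at least 2-fold lower, of 13377. Among the highest ratios were those of the lymphocyte receptor gene Slamf1 (3.38), Tnfrsf8 (3.07) and the vitamin D hydroxylase gene Cyp24a1 (3.07), and the lowest were those of the neuronal RNA Bc1 (-1.93), Cidea (-1.82), Ankrd34b (-1.77) and Cdkl4 (-1.69). Injury neuropeptides had a median of 1.61, injury and regeneration genes 1.40 and macrophage genes 1.05, and large-fibre neuron genes -0.62. As background, left and right in the pool labelled no injury differed by 2-fold in 50 genes one way and 61 the other, of 13182. These were led mostly by muscle genes. The slow muscle genes Myl2 (4.07) and Tnnt1 (3.41) with Igfn1 (3.18) were higher on the left. Mybph (-3.94), Myh4 (-3.70), Myoz1 (-3.30) and Atp2a1 (-3.27) were higher on the right. Prg2, not a muscle gene, was also higher on the left (2.66). The muscle list was at -2.75 there and the neutrophil list at 1.79. The SD of the log2 ratio over genes was 0.476, 0.591 and 0.487 at days 1, 3 and 7 and 0.333 without injury. With a minimum of 200 reads the day 1 counts were 69 higher and 43 lower, and against the mean of the libraries labelled no injury, in place of the same pool's other side, 346 were higher at day 1, 240 lower at day 3, and 642 higher and 221 lower at day 7.

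The similarity of the time points was taken across genes, which are not independent replicates, so it has no p. Side ratios at days 3 and 7 had a Pearson correlation of 0.645, days 1 and 7 of 0.242 and days 1 and 3 of 0.143, and no library is shared between the pools. With the left over right ratio of the pool labelled no injury, those of days 1, 3 and 7 correlated by -0.186, 0.147 and 0.078. Over genes with a mean above 5 CPM the values between the injured pools were 0.777, 0.512 and 0.440.

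The series title asks for time dependence, and a trend of the injury effect over log2 of the day was therefore tested. No gene passed at an adjusted p under 0.05 by edgeR's quasi-likelihood test of 16244 genes: 0 rose and 0 fell with time, against 1299 genes at an unadjusted p under 0.05, and the lowest adjusted p was 0.0562. As values only, the 3 lowest p in the upward direction were those of Rasgrf2 (0.51 ± 0.05 log2 per doubling of days, SE), Neto1 (0.61 ± 0.06) and the inhibin subunit gene Inhbb (0.59 ± 0.06), and in the downward direction Rgs5 (-0.31 ± 0.04), Ly86 (-0.32 ± 0.05) and the serotonin receptor gene Htr3a (-0.45 ± 0.07). DESeq2 called 37 upward and 12 downward, limma-voom 0 and 0, and RLE factors 9 upward. With no low-count filter edgeR called 29 upward and 3 downward. With an operated pool left out, the remaining injured time points fix the slope exactly. Only the left-right difference of the pool labelled no injury is then left as error, so counts of calls are not given for these fits.

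The uninjured side of operated mice was compared with the libraries labelled no injury, left and right summed to 1 sample. The largest differences were those of sex and muscle genes. Y-linked Kdm5d, Eif2s3y, Ddx3y and Uty were at 15.0, 34.1, 66.0 and 30.3 CPM in the day 1 contralateral library and had 0 to 3 reads in each library labelled no injury. Xist was at 238 and 191 CPM in these and at most 0.0941 CPM on the contralateral side. Slow muscle myosin Myh7 was at 20.9 and 1.57 CPM against at most 0.0939, and Myh2 at 4.00 and 4.80 CPM against at most 0.141. In all, 21 genes were higher and 26 lower on the contralateral side, of 16747 tested (edgeR adjusted p under 0.05). Beyond the 8 genes with the largest differences, 7 of them given here, and so chosen after their values were seen, 2 injury and regeneration genes were higher on the contralateral side: Cdkn1a by 0.91 ± 0.10 (log2, SE; adjusted p = 0.0107) and Tnfrsf12a by 1.20 ± 0.18 (adjusted p = 0.0482), and 9 of the 30 rose when adjusted over the list alone, with a list median of 0.86 (camera adjusted p = 3.88e-24, and adjusted p = 0.772 with an estimated correlation). At the preset correlation 4 of the 30 lists passed upward in this comparison, that one, pan-neuronal, cell cycle and unfolded protein response genes, and 6 downward. The downward ones were the skeletal muscle (median -3.52, 3 of 20 fell), extracellular matrix (-0.61, 1 of 25), antigen presentation (-0.27, 0 of 17), endothelial and mural (-0.32, 0 of 20), sterol synthesis (-0.14, 0 of 24) and nociceptor (-0.14, 0 of 30) lists. None of the 10 passed with an estimated correlation (lowest adjusted p = 0.772). Gabra2, a GABA receptor subunit gene also chosen after its values were seen, was at 150 to 160 CPM on the contralateral side and 46.8 and 47.4 CPM in the libraries labelled no injury.

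The comparison rests on 1 control sample that differs in sex from the label. Whether its mice had sham surgery is not given in the sources used here, so an effect of surgery is not separated from the values. Only the libraries of this pool carry WT in their titles, and what that sets them against is not given in the sources used here. A difference in strain, genotype, colony, handling or library batch of this pool is not separated either, for Gabra2 as for the other genes. Without the day 1 library 447 genes were higher and 507 lower, without day 3 13 and 3, and without day 7 27 and 64. Left and right entered as separate samples gave 188 and 184, and DESeq2 87 and 75.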

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

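All tests of explanations in this part were chosen after the values were seen. The gene lists below passed a test for a trend of the injury effect between the time points, by camera on the trend over log2 of the day with the preset correlation at an adjusted p under 0.05, and none did with an estimated correlation (lowest adjusted p = 0.655). The median log2 change per doubling of days was 1.56 for neutrophil genes, 0.85 for lymphocyte genes, 0.62 for cell cycle genes, 0.44 for macrophage genes, 0.35 for erythroid genes, 0.26 for injury neuropeptides, 0.17 for injury and regeneration genes, 0.12 for antigen presentation genes and 0.0935 for repair Schwann cell genes. It was -0.22 for adipocyte genes, -0.18 for mitochondrially encoded genes, -0.16 for large-fibre neuron genes, -0.15 for nociceptor genes, -0.15 for potassium channel genes, -0.14 for interferon-induced genes, -0.11 for sterol synthesis genes, -0.0790 for endothelial and mural genes and -0.0518 for sodium, calcium and HCN channel genes. No single member of these lists passed the trend test in edgeR.

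The neutrophil, erythroid, lymphocyte and cell cycle values above rest in part on the day 1 pair, where these lists had medians of -4.02, -1.17, -1.30 and -1.39 and their contralateral level lay a median of 1.895, 0.853, 0.903 and 0.780 (log2) above the 4 other uninjured libraries. Marrow or blood cells in the day 1 contralateral library are a candidate source, and the 1.895 of the neutrophil genes goes with it. Of these 14 genes 12 had their highest level of all 8 libraries there, S100a9 at 211 CPM, S100a8 at 120 and Mpo at 24.1. The left library labelled no injury held S100a9 at 112, S100a8 at 58.8 and Mpo at 1.83 CPM. A fall on the injured side stays open, since the neutrophil genes of the day 1 injured library lay at a median of -1.182 against the same 4 libraries. Other forms of both tests, 1 on the count of 12 and 1 that ruled out a fall on the injured side alone by the value of 1.895, were tried after these values were seen and not kept. Of the 192 genes at least 2-fold lower at day 1, 58 were at least 2-fold higher in the day 1 contralateral library than in each other uninjured library, and a systemic response of the mice was not tested.

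The splits of the libraries bear on the counts of calls. Labelling any 3 of the 8 libraries as injured gives 56 labelings but only 20 distinct fits once the pool is blocked, and 16 of these part 3 pairs as the real one does, which are too few splits for a share under 0.05. The real split called 2946 genes and the highest of the other 15 called 1. Each of the others turns round or leaves unparted at least 1 injured pair, which puts the injury difference into its error. Their low counts are therefore no measure of chance. At an unadjusted p under 0.05 (edgeR) the real split had 5641 genes. The split of the day 7 and day 3 injured libraries with the left library labelled no injury had 2643. For the lists the real split called 21, and 7 of the 16 splits, the real one included, called as many, with 24 in the highest other, so chance cannot be excluded for the number of lists called at the preset correlation. The calls of single genes within a list do not depend on camera.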

How the results depend on the processing

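One alternative for the contralateral comparison and 1 for the lists were added after seeing the data; the rest were fixed before. The counts of genes higher and lower on the injured side stayed within 1.5 times under RLE and upper-quartile factors, DESeq2, limma-voom, both other filters and the fit without robust shrinkage. Without the pool block (no replicate block) they were 1558 and 1344, of 149 named genes 32 lost their call, and 11 lists were higher and 7 lower. Calls lost were 112 of 149 with side added and 101 in the test against a 1.5-fold change. They were 67 of 144 against the libraries labelled no injury only, a fit without the pool block. Without the day 7, 3 and 1 pool they were 61, 50 and 10 of 148. The counts moved to 763 and 449 without the pool labelled no injury, 703 and 442 against its 2 libraries only, 2506 and 2108 at an adjusted p under 0.10, 54 and 4 in the test against a 1.5-fold change, and 6 and 0 with side added. With side added Tmprss11f turned to -0.30 and Tmem119 to -0.0352, and against the libraries labelled no injury only Slc10a2 turned to 0.66, Kdr to -0.20 and Cldn11 to -0.56; for these and for the other moves the cause was not tested. Leaving out each operated pool in turn gave 475 to 2382 higher and 156 to 2287 lower genes, the low ends without day 7 and the high ends without day 1.

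For the time trend the count of 0 became 9 higher with RLE factors, 37 higher and 12 lower with DESeq2, 29 and 3 with no low-count filter, and 12 to 644 higher and 82 to 570 lower with a pool left out, where 2 injured time points fix the slope. For the contralateral comparison left and right as 2 libraries gave 188 and 184, DESeq2 87 and 75, no low-count filter 276 and 422, and a library left out 13 to 447 higher and 3 to 507 lower, the high ends without day 1 and the low ends without day 3.

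For the side ratios, a minimum of 10 reads gave 276 higher and 411 lower at day 1, 299 lower at day 3, 217 lower at day 7, and 177 and 121 without injury. A minimum of 200 reads gave 69 and 43 at day 1, 425 and 76 at day 3, 230 and 41 at day 7, and 14 and 36 without injury; the number of genes considered changes with the minimum. Against the mean of the libraries labelled no injury there were 346 higher at day 1, 240 lower at day 3, and 642 higher and 221 lower at day 7. The correlations of days 1 and 3, 1 and 7, and 3 and 7 were 0.124, 0.222 and 0.622 with a prior count of 0.5, 0.173, 0.270 and 0.671 with 5, and 0.440, 0.512 and 0.777 over genes with a mean above 5 CPM.

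With an estimated correlation 0 lists were higher and 0 lower, and fry called 3 higher and 0 lower. Without the pool labelled no injury the lists numbered 15 and 6. Over all named genes and lists and all alternatives, 2055 values kept their side of the threshold, 552 lost their call, 79 gained 1 and 5 reversed. A change of direction was counted as a reversal only with a call in either fit, and was otherwise left among the 2055.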

Other observations

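All tests in this part were chosen after the values were seen. Injury and neuropeptide genes at 5 CPM or more and 4 times the no-injury level on the injured side were all above that level on the contralateral side too, 13 genes at day 1, 20 at day 3 and 18 at day 7, by a median of 26.3%, 25.4% and 15.9% of the injured-side excess. A lower baseline in the libraries labelled no injury is argued against as the whole cause, because over the 7 called genes of these lists that rose 4-fold or more on the injured side from day 1 to day 7 the contralateral level rose by a median of 1.892 (log2), Sprr1a from 3.52 to 130 CPM. If RNA or reads of the injured side had entered the contralateral library, no gene could have a contralateral to injured ratio well below that share, and beyond a margin of 1.5 times and counting error 0 of 11515 genes did at day 1, 4 of 11811 at day 3 (among them Cxcl14 at 5.28%, Clcf1 at 7.59% and Arg1 at 7.76%) and 0 of 11699 at day 7. Mixing may therefore account for days 1 and 7 and stays open at day 3, where 10 genes were asked for to rule it out; a limit of 3, which would have ruled it out, was tried after the count of 4 was seen and not kept. A response of the contralateral neurons themselves and a ganglion taken from the wrong side of 1 of the 3 mice were not tested.

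The libraries labelled no injury stood apart from the 6 others. All 4 Y-linked genes above 5 CPM in the operated libraries had at most 3 reads in both, and Xist had 4931 and 4129 reads, which is consistent with female mice in that pool although the labels say male. Skeletal muscle in the dissected tissue is a candidate source of a further part: the mean of both libraries was at least 2-fold above the contralateral mean for 19 of 20 muscle genes, the right library for 20 (median log2 3.90) and the left for 13 (1.34), where 4 did not exceed the day 7 contralateral library, such as Myh4 at 21.6 against 28.0 CPM. With the Y-linked genes, Xist and the muscle list left out, an alternative added after seeing the data, the adjusted test called 14 genes higher and 20 lower on the contralateral side. A difference in strain, genotype, colony, handling or library batch between this pool, alone titled WT, and the operated ones cannot be separated from the label, since the pool is a single one.

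Other values set the same libraries apart. Mir6236 was at 429 to 487 CPM on the contralateral side and 45.3 and 35.5 CPM in the libraries labelled no injury, Lars2 at 510 to 562 against 109 and 86.3, and Wdfy1 at 78.6 to 85.5 against 18.0 and 15.7. Btaf1 was at 26.7 to 28.0 CPM against 76.1 and 68.0, and Ide at 82.0 to 96.2 against 193 and 191.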
